A study of Mus musculus with 23 samples.

How the data were processed

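The assay for transposase-accessible chromatin with sequencing (ATAC-seq) marks open chromatin by the places where the Tn5 transposase inserts adapters. Per the labels, maxillary prominences of wild-type C57BL/6 mouse embryos were dissected at embryonic day 10.5 (E10.5), E11.5 or E12.5, the ectoderm was peeled off after Dispase treatment, and the mesenchymal cells went into transposase libraries. The 23 library runs belong to 9 biological samples, 3 per stage, with 1 to 4 runs per sample, and 1 peak list per sample was used here. The number of embryos behind a sample is not given in the sources used here.

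The submitters' processing notes name Bowtie2, deepTools 3.3.1 and MACS2 with the mm10 build, and per the labels the peaks were called from paired-end alignments and blacklisted regions were removed. How reads were filtered or shifted for the transposase offset, and the threshold given to MACS2, are not given in the sources used here. Each deposited list gives every peak's position and summit, a fold enrichment over background at the summit (a ratio), and the −log10 p-value and −log10 q-value of the authors' peak caller. These values are the authors' own and were used only to describe, rank or filter peaks within a list. The smallest deposited −log10 q lay between 1.30 and 1.32 in every list.

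The lists hold no read counts, so sequencing depth is not known directly. The background coverage was worked out from the deposited fold and −log10 p of each list, assuming that the fold is (pileup + 1) / (background + 1) and the p-value a Poisson tail, and it is used only as a description of depth. No read-level precision can be given. The error of every statement comes from the 3 lists per stage, except for the 95% interval of the rank group test, which is taken over regions.

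Peaks on the 19 autosomes and chromosome X that overlapped by at least 1 bp were merged into regions across the 9 lists, and each list was scored as calling a region or not. Longer lists call more regions, so the number of calls expected in each list came from an additive logit model of list and region (a Rasch model), conditional on how many of the 9 lists called the region. A region was gained when all 3 lists of the later stage and none of the earlier stage called it, and lost in the opposite case. Regions were assigned to the protein-coding gene, among 21627 in a RefSeq annotation of GRCm38.p6, whose start or end lay nearest to the strongest summit within 100 kb. The annotation used gives no strand, so distances planned from transcription start sites were taken from the nearest gene boundary, start or end, and a region was classed as near a boundary within 1 kb. Exons, introns and untranslated regions could not be separated. All 352 genes of the gene lists were found in the annotation.

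For genes with 5 or more regions called by 1 to 8 lists, calls minus expected calls were divided by the root of the expected variance. These residuals were tested with limma 3.58.1 (R 4.3.3) with stage as a factor over all 9 lists and Benjamini-Hochberg adjustment at 0.05. The numbers of regions per gene given below hold only such regions, so a region called by all 9 lists is not among them. For 20 gene lists (14 of pathways and 6 of cell type markers), log2 of calls over expected calls, each with 0.5 added, was tested for a slope per day by an exact two-sided permutation test over the 1680 assignments of stages to lists. Similarity was the Jaccard index of called regions, with a one-sided exact test over the 280 partitions into trios. With 3 lists against 3, no exact two-sided test can give a p under 0.1. The exact p-values measure the spread between these samples. Those of limma rest mostly on a variance pooled over genes (prior degrees of freedom 265.3), so a gene's own spread between lists weighs little in them. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

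The model and the test were tested on simulated calls. With no change, the number of gained or lost regions was 0.939 to 1.07 times the expected number, and limma called 0 of 7365 genes for E12.5 against E10.5. With the odds of a call in the E12.5 lists changed 8-fold in 100 genes and 32-fold in 100 others, 31% and 59% were recovered in that comparison, with 6 wrong calls among 96. The changed genes were drawn only from the 3039 tested genes with 10 or more regions. Recovery in genes with 5 to 9 regions was therefore not simulated. The simulated calls came region by region from the same fitted model, so numbers near the expected ones with no change follow by construction. No further spread between libraries was simulated, whereas other groupings of the real lists into trios reached 45 and 50 genes. The simulation therefore does not show how often the real lists give wrong calls.

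The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Named genes are members of the gene lists that pass the gene test; the genes with the smallest adjusted p per direction, 10 for E12.5 against E10.5 and 5 for adjacent stages, or where none pass those with an excess of at least 3 gained over lost regions or the reverse; the 5 gained and 5 lost regions for E12.5 against E10.5 that ranked highest in all calling lists; and up to 4 members of each gene list with the most gained or lost regions. Other names are said to have been chosen after their values were seen. Alternatives were equal-length lists of 5682 peaks, a −log10 q of at least 5, windows of 501 bp around summits, a reciprocal overlap of 50%, a boundary class of 2.5 kb, a limit of 20 kb to the nearest boundary, calling odds fitted separately by boundary class, regions called by 2 to 8 lists, genes with 10 or more regions, the sample number as a block, and each list left out. Leaving out chromosome X was added after seeing the data. The planned search for transcription factor motifs was not run, because no genome sequence was used here.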

Results

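Chromatin accessibility was profiled by ATAC-seq in the mesenchyme of the mouse maxillary prominence, the embryonic tissue that forms the upper jaw and the palatal shelves, at E10.5, E11.5 and E12.5. The wider series follows how this tissue develops and which regulators act in it. Each stage had 3 biological samples and each sample 1 peak list. The lists held 16057, 19095 and 14886 peaks at E10.5, 5682, 24908 and 41457 at E11.5, and 26584, 50361 and 19139 at E12.5. The background coverage implied by the peak scores was 5.19, 10.1 and 11 fragments per base at E10.5, 1.76, 1.83 and 5.24 at E11.5, and 3.57, 10.7 and 6.40 at E12.5, so that the E11.5 samples 1 and 2 had the shallowest background. The highest fold in each E11.5 list was 17.9 to 20.4, against 5.83 to 7.47 at E10.5 and 6.62 to 14.7 at E12.5, and the highest −log10 q was 116 to 145 at E11.5 and at most 60.1 elsewhere. The median fold per list was 2.56 to 3.13 at E10.5, 3.13 to 5.06 at E11.5 and 2.47 to 3.50 at E12.5. The peak names begin with a number, which was 489, 534 and 596 at E10.5, 227, 239 and 312 at E11.5, and 319, 572 and 600 at E12.5. All E11.5 lists thus carry low numbers and all E10.5 lists high ones. The meaning of these numbers is not given in the sources used here, and if they mark batches, E11.5 cannot be told apart from its batch.

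Peaks near gene boundaries made up 39.2% ± 1.89 of the E10.5 lists, 48.5% ± 21.8 of the E11.5 lists and 20.6% ± 7.22 of the E12.5 lists (SD, n = 3 each). The slope was -9.29 percentage points per day (exact permutation test, two-sided, p = 0.194). All 3 E12.5 lists lay below all 3 E10.5 lists, which is the most that 3 against 3 can show (exact p = 0.1). The mean number of peaks per list was 16679 ± 2172, 24016 ± 17904 and 32028 ± 16307 at the 3 stages, and the slope of 0.41 on the log2 scale per day did not pass the test (exact p = 0.314). All 3 E12.5 lists were also longer than all 3 E10.5 lists (exact p = 0.1), the shortest with 19139 peaks against 19095 in the longest E10.5 list. List length and boundary share thus moved together between these stages. In equal-length lists the share was 59.9% to 65.5% at E10.5, 73.0% to 79.5% at E11.5 and 24.5% to 45.9% at E12.5. E12.5 minus E10.5 was then -27.9 percentage points (exact p = 0.1). All 3 E12.5 lists stayed below all 3 E10.5 lists, which argues against list length alone as the cause of the lower E12.5 share. The slope in equal-length lists did not pass the test (-13.97 percentage points per day, exact p = 0.0619). The slope of the boundary share passed the test with peaks of a −log10 q of at least 5 (slope -15.3 percentage points per day, exact p = 0.0238). It also passed without E11.5 sample 1 (slope -9.29, exact p = 0.0214). With 3 lists at each end the E11.5 lists have no weight in this slope. Leaving out that list thus kept the slope by construction and changed only the values that were permuted.

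**Figure D1:**
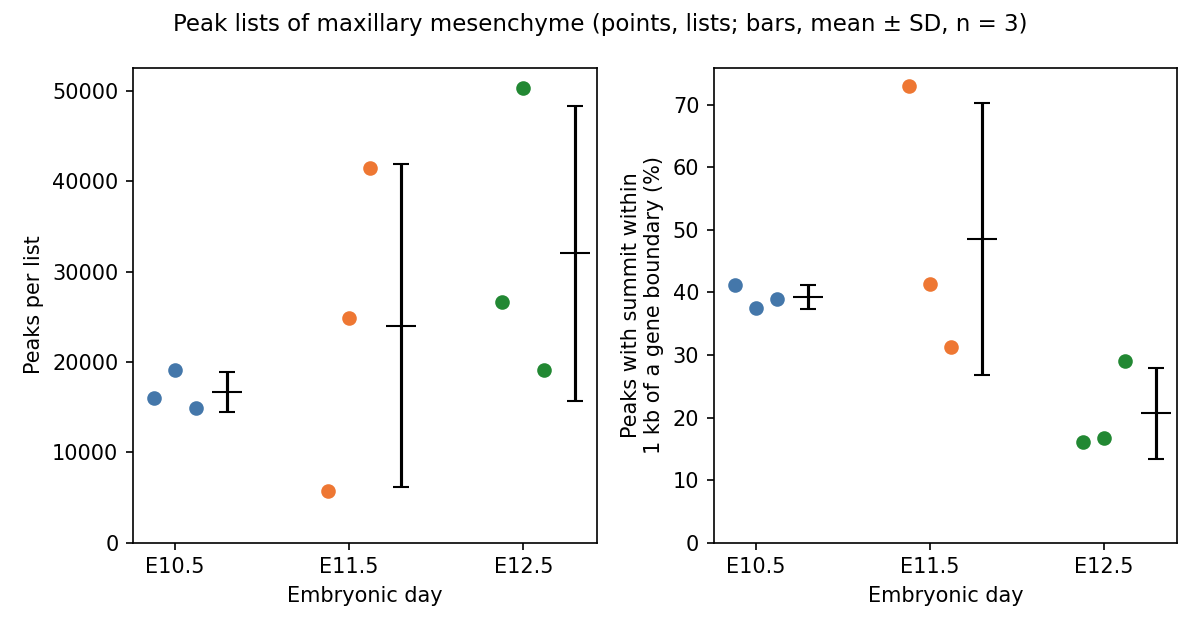
Number of peaks per list (left) and percent of peaks with the summit within 1 kb of a gene boundary (right) against embryonic day; points are lists and bars are the mean ± SD of 3 lists. The 3 E12.5 lists lie between 16.2% and 29.0%, below the 3 E10.5 lists at 37.5% to 41.2%.

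The 9 lists merged into 118102 regions, of which 81231 were called by a single list and 1206 by all 9. Of the regions called by all lists 84% lay near a gene boundary, against 7.51% of those called by 1 list. At least 2 of 3 lists called 9679 regions at E10.5, 14453 at E11.5 and 15731 at E12.5, and 3965 regions met this at every stage. Averaged over all pairs, lists of the same stage shared more regions than lists of different stages. The mean Jaccard index was 0.201 within and 0.154 between stages (difference 0.0474, exact one-sided p = 0.0036 over 280 partitions, the smallest they can give). The mean index was 0.252 among the E10.5 lists, 0.213 among the E11.5 lists and 0.139 among the E12.5 lists. These are not ranked, since lists of unequal length limit the index: E11.5 samples 1 and 3 gave 0.133 and samples 2 and 3 gave 0.294, above the highest E10.5 pair (0.264). The mean between E10.5 and E12.5 lists was 0.153, between E10.5 and E11.5 lists 0.197 and between E11.5 and E12.5 lists 0.111. By this index the E12.5 lists were on average no closer to each other than to the E10.5 lists. Unequal list length limits this comparison too, so it does not show how alike the stages are. E12.5 sample 3 had 0.199, 0.212 and 0.189 with the E10.5 lists, but 0.110 and 0.146 with E12.5 samples 1 and 2. That sample called 18312 regions, within the 13864 to 18645 of the E10.5 lists, against 25349 and 48768 in E12.5 samples 1 and 2. Without E11.5 sample 2 the difference within minus between stages was 0.0315 (exact one-sided p = 0.0571).

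Between E10.5 and E12.5, 565 regions were gained and 362 were lost. List calling odds alone gave 611.5 gained and 47.7 lost regions, so that losses were 7.59 times and gains 0.924 times the expected number. Of the lost regions 72.4% lay near a gene boundary, and of the gained regions 10.1%. Among the lost regions with the highest ranks were those on chromosome 6 at 57534815 to 57536056, next to Ppm1k, a mitochondrial phosphatase gene of branched-chain amino acid breakdown, and on chromosome 13 at 103773962 to 103774786, inside Srek1, a splicing regulator. Others lay on chromosome 2 at 23067940 to 23069538, inside Acbd5, a peroxisomal membrane protein gene, and on chromosome 4 at 95966917 to 95967691, next to Hook1, a microtubule-linked adaptor gene. These 4 were called by all 6 lists of E10.5 and E11.5. The 1 other of the 5 highest is not described here. The gained regions with the highest ranks lay on chromosome 10 at 115170829 to 115171242, inside Tph2, a serotonin synthesis gene; on chromosome 2 at 174330454 to 174330884, inside the imprinted Gnas gene. The others lay on chromosome 11 at 95713451 to 95714152, 32.8 kb from Phb; on chromosome 15 at 86945778 to 86946190, 447.5 kb from the nearest boundary, that of Tbc1d22a; and on chromosome 19 at 4982706 to 4983071, 1.45 kb from Npas4. Each of these was also called by E11.5 sample 3. All coordinates are on mm10. With 1 list of a stage left out, 2 lists decide and counts rise by construction: lost regions numbered 792, 646 and 970 without E10.5 samples 1, 2 and 3 (2.31, 2.35 and 2.59 times the expected number), and 432, 856 and 621 without E12.5 samples 1, 2 and 3 (4.81, 4.63 and 7.87 times), and with calling odds fitted by boundary class the 362 were 3.22 times the expected number. Gained regions numbered 2313, 866 and 5040 without E12.5 samples 1, 2 and 3 (1.04, 0.703 and 1.51 times the expected number), and 29 at a −log10 q of at least 5.

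No gene passed the test between E10.5 and E12.5 with limma, with 658 of 7365 genes at an unadjusted p under 0.05. Among the 219 tested entries of the 20 gene lists, 9 genes passed when adjusted over the list alone. In the maxillary and palate patterning list these were Tbx3 and Foxf1 with more calls and Tbx15 and Meis1 with fewer, of 14 tested members. Of the 22 regions of Bmp7, a bone morphogenetic protein gene, that 1 to 8 lists called, 0 were called in any E10.5 list, where a mean of only 1.90 was expected. At E12.5 the number was 7 ± 3 against 4.56 expected (residual difference 2.93 ± 0.833 SE, limma adjusted p = 0.207 over all genes and 0.0071 over the list alone). Eln (elastin) and Pax7, a myogenic and neural crest factor, also had more calls over their lists alone, and Mef2c and Fgfr2 fewer. Tbx3, Foxf1, Eln, Fgfr2 and Pax7 were chosen after their values were seen. Cdh4, the R-cadherin gene, was the one gene with an excess of 3 gained regions, with 13.7 ± 4.93 of 37 regions called at E12.5 and 3.67 ± 3.06 at E10.5, against 9.10 and 4.03 expected (adjusted p = 0.373). No gene had an excess of 3 lost regions. Among members of the lists with 1 gained region were Sox6, Col6a2, Fzd2, Fgf9, Rarb and Grhl2, and with 1 lost region Twist2, Boc and Sall4, none of which passed the test. Counting only regions called by 2 to 8 lists, 29 genes had more and 3 fewer calls; at a −log10 q of at least 5 the counts were 4 and 0, with equal-length lists 3 and 0, without E12.5 sample 3 3 and 1, and without E12.5 sample 2 1 and 0.

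**Figure D2:**
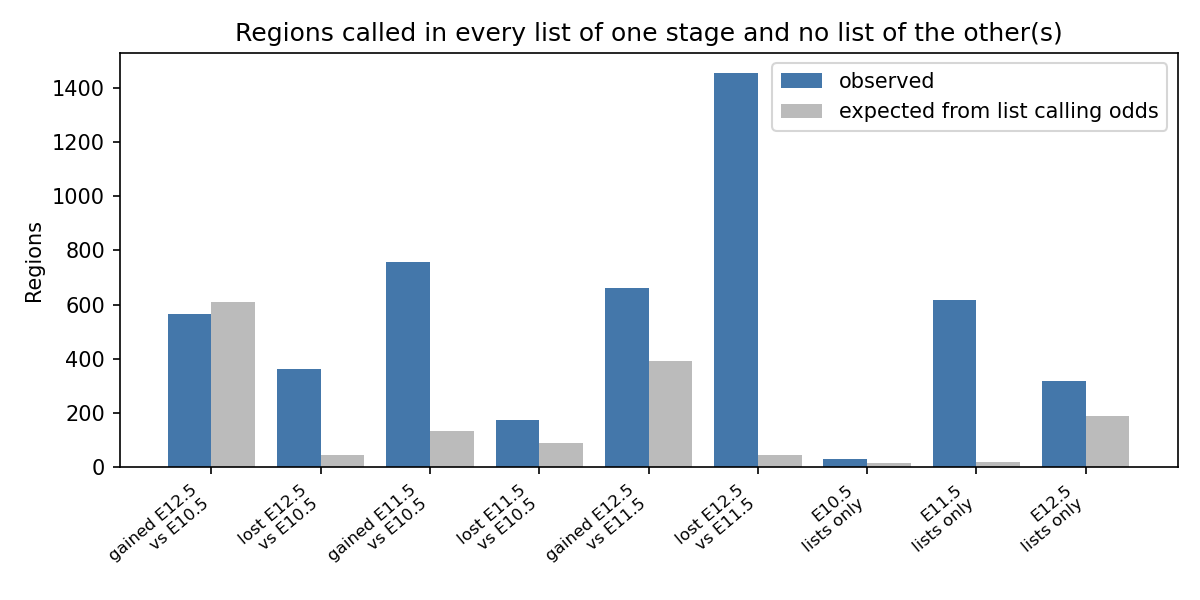
Number of regions called in every list of one stage and in no list of the other stage, or of both other stages (lists only), observed and expected from list calling odds. As ratios, losses from E11.5 to E12.5 (1455 against 45.9) and regions of E11.5 lists only (618 against 21.99) exceed the expected numbers most.

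Between E10.5 and E11.5, 759 regions were gained against 133.3 expected and 176 were lost against 89.0 expected. Regions near Mef2c, a transcription factor gene of muscle and craniofacial development, were called more often at E11.5 (7 ± 4 of 12 regions) than at E10.5 (2 ± 0), with 2.91 and 2.17 expected (residual difference 3.63 ± 0.848 SE, limma adjusted p = 0.034). Robo1, an axon guidance receptor gene, had 4.67 ± 3.79 of 13 regions called at E11.5 and 0 in every E10.5 list, against 1.89 and 1.09 expected. Btbd3 and Cxxc4, the latter an inhibitor of Wnt signalling, also passed with more calls at E11.5 (adjusted p = 0.034 each). Dnhd1, a dynein heavy chain domain gene, and Atp6v0a2, a subunit gene of the vacuolar proton pump, passed with fewer. Atp6v0a2 had 5 ± 0 of 8 regions called at E10.5 and 1.33 ± 1.53 at E11.5, against 2.80 and 3.14 expected. The highest fold per list also differed between these stages, at 5.83 to 7.47 and 17.9 to 20.4.

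In all, 4 genes had more and 2 fewer calls at E11.5 than at E10.5. Of the gene list members, Mef2c passed over all genes, and 7 genes passed when adjusted over the list alone: Mef2c, Trps1, Fgf10 and Etv1 with more calls and Hoxb9, Hoxb13 and Fli1 with fewer, of which Etv1, Hoxb9, Hoxb13 and Fli1 were chosen after their values were seen. Fgf10, a ligand gene of epithelial and mesenchymal signalling, had 1, 10 and 3 of 10 regions called in the 3 E11.5 lists against 0.39, 2.15 and 3.3 expected (adjusted p = 0.0769 over all genes). Epcam, an epithelial adhesion gene, had 2 gained regions, and its residual difference of 2.05 did not pass (adjusted p = 0.408). Prrx1, Tbx15, Boc and Fzd2 had 1 lost region each and Sparc, Trps1, Nkd1, Etv5 and Crabp2 1 gained region each, without passing. The calls depended on single lists: 1 gene had more and 3 fewer calls without E10.5 sample 1, 1 and 0 without E11.5 sample 1, E11.5 sample 2 or E12.5 sample 2, 25 and 0 without E11.5 sample 3, and 0 and 0 without E10.5 sample 2, E10.5 sample 3, E12.5 sample 1 or E12.5 sample 3, where the E12.5 lists enter through the shared model; the counts were also 0 and 0 with the nearest boundary within 20 kb, equal-length lists or a −log10 q of at least 5, 1 and 5 with regions called by 2 to 8 lists, and 1 and 0 with genes of 10 or more regions. Gained regions, 5.69 times the expected number, numbered 5434, 789 and 876 without E11.5 samples 1, 2 and 3 (2.11, 1.85 and 3.20 times) and 760 at a −log10 q of at least 5 (2.48 times), and lost regions, 1.98 times, numbered 676, 496 and 754 without E10.5 samples 1, 2 and 3 (1.39, 1.26 and 1.42 times), 724 and 218 without E11.5 samples 3 and 2 (2.15 and 0.966 times), 223 with equal-length lists (3.01 times) and 13 at a −log10 q of at least 5 (3.67 times).

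Between E11.5 and E12.5, 1455 regions were lost against 45.9 expected and 662 were gained against 393.2 expected. With odds fitted by boundary class 176.4 lost regions were expected, which lowers the ratio from 31.7 to 8.25. Of the lost regions 64.6% lay near a gene boundary and of the gained 9.67%. Of the 12 regions of Mef2c that 1 to 8 lists called, 0 were called in any E12.5 list (3.92 expected) after 7 ± 4 at E11.5. This was the largest difference of the named genes (residual difference -6.27 ± 0.848 SE, limma adjusted p = 1.28e-08). Etv1, an effector gene of FGF signalling, had 3.67 ± 2.52 of 6 regions called at E11.5 and 0 in every E12.5 list, against 1.51 and 2.03 expected (adjusted p = 0.000498). Fgf10 had 4.67 ± 4.73 and 0.667 ± 0.577 of 10 regions called at E11.5 and E12.5, against 1.95 and 2.67 expected (adjusted p = 0.00208). The highest fold per list was 17.9 to 20.4 at E11.5 and 6.62 to 14.7 at E12.5.

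Of the gene lists, 7 members had fewer calls at E12.5 than at E11.5 and 2 had more. In the osteogenic list, 2 of 12 tested members had fewer calls, Mef2c and the type I collagen gene Col1a2 (adjusted p = 0.0173), and 0 had more. Both FGF pathway members that passed, Etv1 and Fgf10, of 17 tested, had fewer. The chondrogenic list had 1 of 11 with fewer calls, Trps1, a repressor gene of skeletal growth (adjusted p = 0.00641). The Wnt list had 1 of 18, Rspo2, which encodes a secreted Wnt enhancer (adjusted p = 0.0214), and the patterning list 1 of 14, Meis1, a TALE homeodomain factor gene (adjusted p = 0.0247). The odontogenic list had Fgf10 alone of 12. With more calls were Erg, an endothelial transcription factor gene, with 14 ± 7.94 of 43 regions at E12.5 and 3.67 ± 5.51 at E11.5, against 9.67 and 6.87 expected (adjusted p = 0.0187), and Pax7, with 9.67 ± 6.11 of 29 regions and 1.67 ± 2.89, against 6.01 and 4.23 expected (adjusted p = 0.0202). For Erg the E12.5 lists had 17, 20 and 5 called against 7.54, 16.51 and 4.96 expected, so that sample 3 lay at the expected number. The same held for Pax7, with 11, 15 and 3 called against 4.57, 10.52 and 2.94 expected. Both genes had 0 gained regions, that is, no region called by all 3 E12.5 lists and by no E11.5 list. These sums also count regions that a single list called, so they do not show the same regions called across the E12.5 lists. Erg and Pax7 were the 1 of 9 tested endothelial markers and the 1 of 6 tested myogenic markers that passed. Among the alternatives that tested each gene, the call was lost in 5 of 16 for Meis1 and Pax7, 4 of 16 for Fgf10, 4 of 14 for Rspo2, 4 of 18 for Erg, 2 of 14 for Trps1, 1 of 16 for Mef2c and 1 of 12 for Col1a2, with an adjusted p of up to 0.587 (Pax7). In the other 12 lists (cranial neural crest, hedgehog, BMP and TGF-beta, retinoic acid, early timing, cell cycle, extracellular matrix, Hox, epithelial, neuronal, blood and pericyte) 0 members passed with limma, where 1204 of all genes had an unadjusted p under 0.05. In all, 17 genes passed when adjusted over the list alone, where Tbx3, Foxf1, Dlx3, Eln, Itgam and Notch3 had more and Sparc and Abcc9 fewer calls in addition; these were chosen after their values were seen, except Tbx3 and Sparc.

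Over all genes, 69 had more and 117 fewer calls at E12.5 than at E11.5. The lost regions numbered 6810, 1503 and 1589 without E11.5 samples 1, 2 and 3 (4.58, 7.11 and 12.0 times the expected number), 2060 without E12.5 sample 2 (13.3 times), 1446 with equal-length lists (18.3 times) and 1521 at a −log10 q of at least 5 (5.48 times, 277.4 expected); the gained regions, 1.68 times the expected number, numbered 683 and 1630 without E11.5 samples 2 and 3 (0.918 and 1.64 times), 2667, 972 and 4796 without E12.5 samples 1, 2 and 3 (1.64, 1.11 and 1.90 times), and 30 at a −log10 q of at least 5 (10.3 times). The smallest adjusted p among genes with more calls belonged to Ajap1, an adherens junction gene, with 14 ± 6.56 of 39 regions called at E12.5 and 2.33 ± 2.52 at E11.5 (against 8.35 and 5.90 expected; residual difference 4.03 ± 0.834 SE, adjusted p = 0.00185). Of the regions of Ajap1, 1 was gained. With the nearest boundary within 20 kb the difference of Ajap1 was -0.076. The axonemal dynein gene Dnah8, Cdh4 and the melanosome transport gene Myrip followed. Among genes with fewer calls, Cxxc4, Btbd3, Pecr, a peroxisomal enzyme gene of fatty acid chain elongation, and the metalloproteinase gene Adamts6 followed Mef2c. Pecr had 4, 5 and 5 of 8 regions called in the 3 E11.5 lists and 0, 3 and 0 in the E12.5 lists, against means of 2.72 and 3.54 expected. Without E11.5 sample 2, 3 genes had more and 13 fewer calls; without E12.5 sample 1 the counts were 29 and 48, without E12.5 sample 2 69 and 27, and without E11.5 sample 3 20 and 119; the counts also moved with the regions used, to 168 more and 27 fewer with regions called by 2 to 8 lists, to 46 and 1 at a −log10 q of at least 5, to 43 and 19 with genes of 10 or more regions, to 19 and 117 with odds by boundary class, to 0 and 8 with the nearest boundary within 20 kb and to 6 and 0 with equal-length lists.

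**Figure D3:**
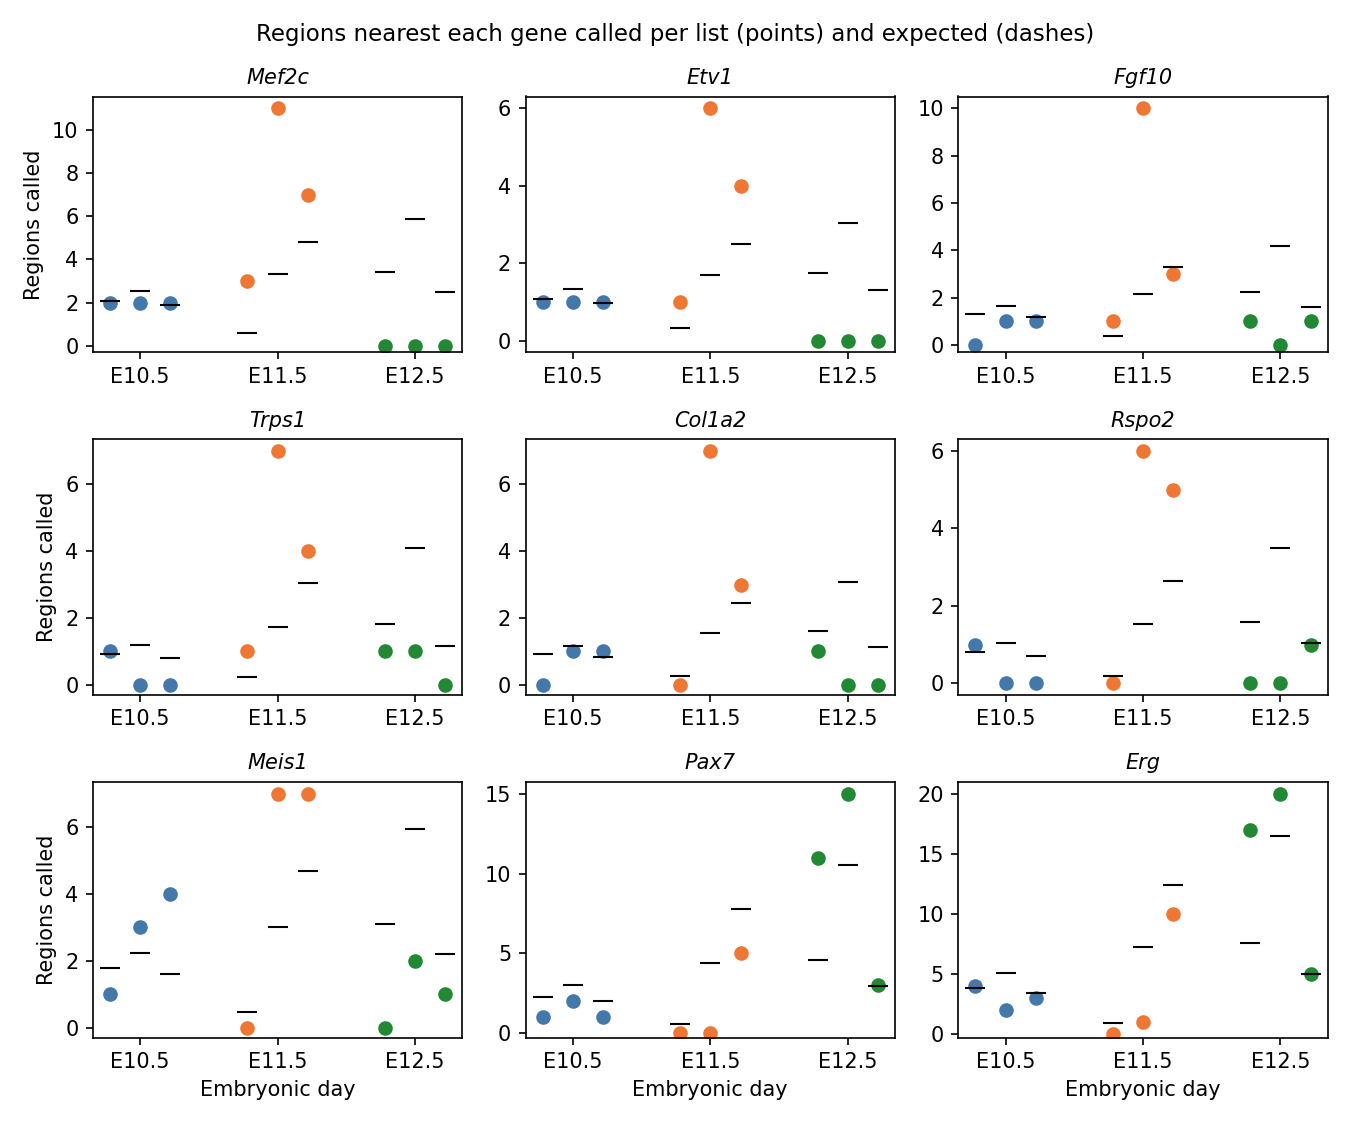
Number of regions nearest each gene that each list called (points) and the number expected from list calling odds (dashes), against embryonic day, for the 9 gene list members that passed the test between E11.5 and E12.5. Regions called by all 9 lists are not counted. Mef2c has 3, 11 and 7 called regions in the E11.5 lists and 0 in each E12.5 list, and Erg has 17, 20 and 5 in the E12.5 lists.

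The regions called by all lists of one stage and by no other list numbered 33 at E10.5, 618 at E11.5 and 318 at E12.5, against 14.7, 21.99 and 188.2 expected. The E11.5 ratio of 28.1 was the highest of the 84 trios of lists, and the highest of the other trios was 3.29; with odds fitted by boundary class the ratio was 12.2 and the highest other 2.37, and at a −log10 q of at least 5 it was 5.10. Of the E11.5 regions 51.6% lay near a gene boundary and 7.44% on chromosome X, and of the E12.5 regions 7.55% and 0.314%. Among peaks near boundaries, chromosome X held 3.15% ± 0.282 at E11.5, 1.56% ± 0.829 at E10.5 and 1.41% ± 0.480 at E12.5 (exact p = 0.1 for E11.5 against either stage). Without chromosome X, chosen after seeing the data, the E11.5 regions numbered 572 against 20.5 expected. The E11.5 regions numbered 4604, 656 and 729 without E11.5 samples 1, 2 and 3 (4.27, 4.72 and 8.53 times the expected number) and 681 without E12.5 sample 2 (15.1 times). The E10.5 regions, 2.25 times the expected number, numbered 224, 143 and 230 without E10.5 samples 1, 2 and 3, but their ratio fell to 1.24, 1.01 and 1.15. They numbered 52 without E11.5 sample 3 and 72 without E12.5 sample 2 (2 and 2.40 times). The E12.5 regions, 1.69 times the expected number, numbered 1628, 552 and 3697 without E12.5 samples 1, 2 and 3 (1.48, 1.02 and 2.13 times) and 533 without E11.5 sample 3 (1.69 times). They numbered 59 with equal-length lists and 14 at a −log10 q of at least 5 (2.73 and 9.91 times).

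None of the 20 gene lists had a stage slope past the threshold. The smallest unadjusted p belonged to the epithelial markers, at 0.292 on the log2 scale per day (exact p = 0.083, adjusted p = 0.671), and to the retinoic acid pathway, at 0.235 (exact p = 0.087, adjusted p = 0.671). Calls near epithelial genes were -0.32 ± 0.166 on the log2 scale relative to the expected number at E10.5, -0.322 ± 0.568 at E11.5 and 0.264 ± 0.123 at E12.5, although the ectoderm had been peeled off. The cranial neural crest list went from 0.233 ± 0.167 at E10.5 to -0.205 ± 0.316 at E12.5 (slope -0.22, exact p = 0.201). The myogenic markers had 0.248 ± 0.228 and the blood and macrophage markers 0.325 ± 0.191 at E12.5, against -0.186 ± 0.291 and -0.222 ± 0.162 at E10.5, with exact p = 0.182 and 0.185. The chondrogenic (0.045), osteogenic (-0.043), odontogenic (-0.06), extracellular matrix (0.086), hedgehog (0.056), Wnt (0.048), BMP and TGF-beta (0.071), FGF (-0.105), cell cycle (-0.08), early timing (-0.225), patterning (-0.09), neuronal and glial (-0.111), endothelial (0.141), Hox (-0.244) and pericyte (-0.022) lists had slopes with exact p between 0.162 and 0.874.

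**Figure D4:**
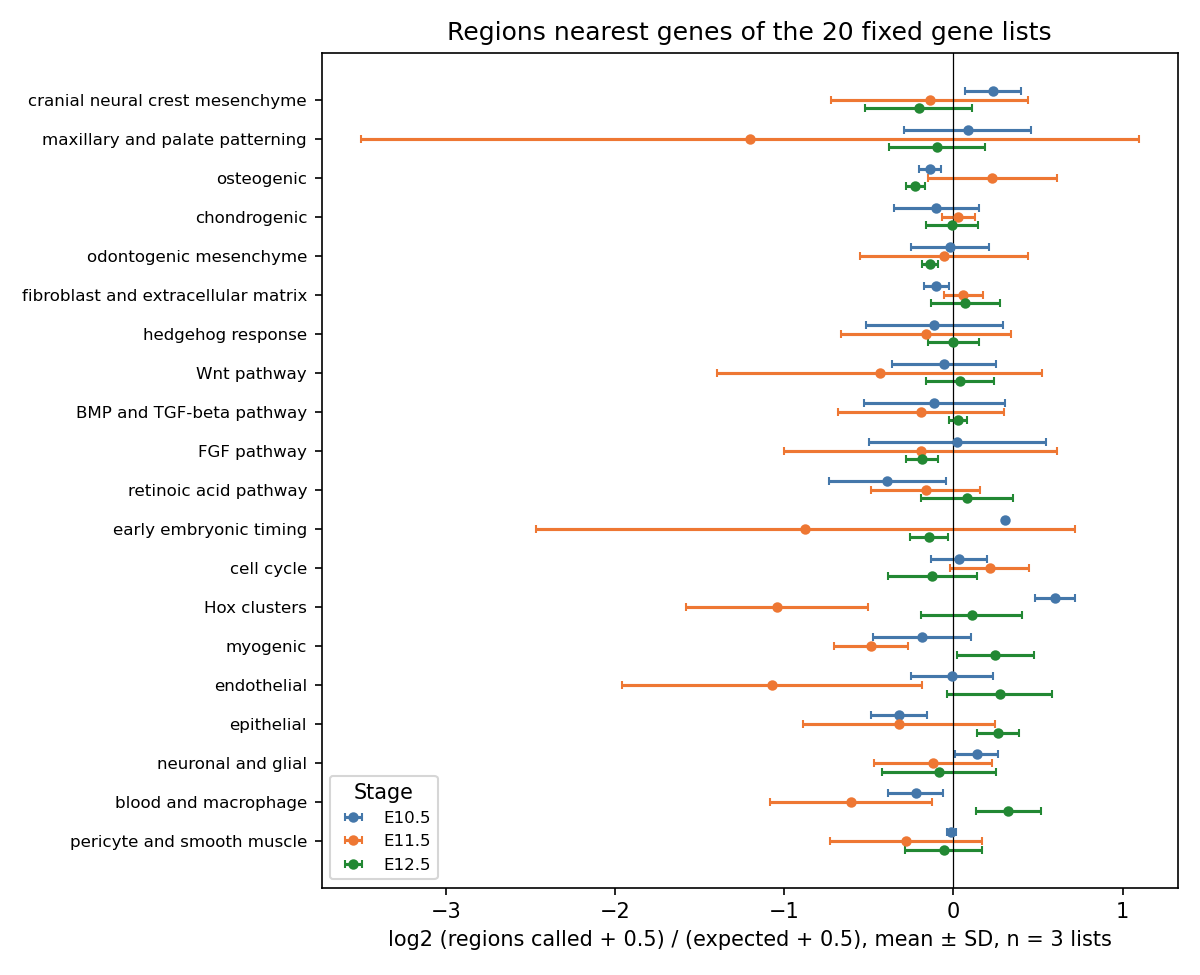
Log2 of regions called over regions expected (0.5 added to each) for the genes of 20 lists, as mean ± SD of 3 lists per stage. The Hox clusters lie at 0.598 at E10.5, -1.04 at E11.5 and 0.109 at E12.5, and no list has a slope past the threshold.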

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

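Leaving out chromosome X was chosen only after the data were seen, and it kept every count of regions and genes within 1.5 times. The similarity within stages kept its direction under all alternatives run, and its side of the threshold under all but the omission of E11.5 sample 2 (0.0315 to 0.0721 with each list left out). The 0 gene lists with a stage slope stayed 0 under all alternatives run. With a −log10 q of at least 5 the slope of peaks per list was -0.028 and that of the boundary share -15.3, gained and lost regions were 29 gained (E12.5 against E10.5), 13 lost (E11.5 against E10.5) and 30 gained (E12.5 against E11.5), and 4 and 14 regions were called in E10.5 and E12.5 lists only. Gene counts were then 4 more (E12.5 against E10.5), 0 and 0 (E11.5 against E10.5) and 1 fewer (E12.5 against E11.5). With equal-length lists the counts were 63 gained (E12.5 against E10.5), 167 gained (E12.5 against E11.5), 60 and 59 (E10.5 and E12.5 lists only), and 3 genes more, 0 and 0, and 6 more and 0 fewer in the same order of comparisons. These settings test 437 and 363 genes against 7365. With the nearest boundary within 20 kb, 0 and 0 genes passed for E11.5 against E10.5, and 0 more and 8 fewer for E12.5 against E11.5, where the difference of Ajap1 turned to -0.076. With regions called by 2 to 8 lists the counts were 29 more and 3 fewer, 1 and 5, and 168 and 27, with genes of 10 or more regions 1 and 0 for E11.5 against E10.5 and 43 and 19 for E12.5 against E11.5, and with calling odds by boundary class 19 more for the latter. The cause was not tested beyond the number of genes. With each list left out, the slope of peaks lay between 0.214 and 0.536 and that of the boundary share between -11.1 and -6.82. Gained and lost regions then lay between 565 and 5040 and between 362 and 970 (E12.5 against E10.5), 759 and 5434 and 173 and 754 (E11.5 against E10.5), and 658 and 4796 and 1454 and 6810 (E12.5 against E11.5); those of single stages between 33 and 230, 638 and 4604, and 319 and 3697. Genes with more and fewer calls lay between 0 and 3 and 0 and 1, 0 and 25 and 0 and 3, and 3 and 87 and 13 and 119. The 6 genes named between E10.5 and E11.5 passed in 4 to 7 of their alternatives, while Etv1, Btbd3 and Pecr passed in all of theirs between E11.5 and E12.5.

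Sample numbers pair no lists, since correlations of same-numbered lists lay between -0.078 and 0.022. With the sample number as a block, 70 genes had more and 121 fewer calls between E11.5 and E12.5, 4 and 2 between E10.5 and E11.5, and 0 and 0 between E10.5 and E12.5 (631 at an unadjusted p under 0.05 with limma), and no call on a list value changed. Equal-length lists give no number of peaks to compare, and the motif search was not run. The depth is unknown and 3 lists per stage limit every count.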

Other observations

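The test of the Hox list and the test of single libraries were chosen only after their results were seen, as were the counts of splits and trios and the demand that the whole interval of the rank group test clear its bound; the other tests below were written before. Hox genes, which pattern the trunk and are silent in the maxillary prominence, had calls below the expected number in the E11.5 lists (-1.04 ± 0.537 on the log2 scale, SD, n = 3) and on average above it in the other 6 (0.354 ± 0.336), of which E12.5 sample 2 lay below it (35 called, 39.6 expected). All 3 E11.5 lists lay below all others (exact p = 0.0119 over 84 trios, the smallest they can give), and the value adjusted over the 20 lists was 0.159, so this did not pass. Endothelial markers had -1.07 ± 0.886 in the E11.5 lists against 0.133 ± 0.294 in the others (exact p = 0.0238, adjusted p = 0.159), blood and macrophage markers -0.604 ± 0.478 against 0.0514 ± 0.339 (exact p = 0.0476, adjusted p = 0.238), each with 2 of the 3 E11.5 lists below all others, and osteogenic genes 0.231 ± 0.379 against -0.182 ± 0.0719 (exact p = 0.0238, adjusted p = 0.159), none of which passed.

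The 618 regions that all E11.5 lists and no other list called were 28.1 times the expected number. The ratio was 12.2 with odds fitted by boundary class and 5.10 at a −log10 q of at least 5. Of the 84 trios, only the E11.5 trio reached 28.1, and the highest other was 3.29 (2.37 with odds by boundary class). No other trio of these lists thus came near this ratio. A share of 1 of 84 is the smallest this test can give. It was not adjusted over the tests chosen after the data were seen, so chance is not excluded. Of sequence in several copies, only families of neighbouring genes could be looked at. Of the regions, 8.58% lie nearest a gene with a same-stem neighbour within 500 kb. The share was 6.62% of other regions called in all E11.5 lists and 5.14% of regions called in all 9 lists. This argues against such gene families as the source of most of the regions. Other repeated sequence could not be tested without a genome sequence and is left open. A batch that joins E12.5 sample 1 to the E11.5 lists by the numbers in the peak names predicts many regions called by these lists alone. They were 2.04 times the expected number, the lowest of the 6 other lists. The other E12.5 lists gave 2.46 and 3.43, and the E10.5 lists 30.9, 25.65 and 17.4. The ratios thus follow the stage, so this test cannot decide on such a batch. A higher signal over background in the E11.5 libraries is left open. The highest fold was 17.9 to 20.4 in these lists and at most 14.7 in the others. The median fold was 5.06, 4.98 and 3.13 in E11.5 samples 1, 2 and 3. It was 2.47 to 3.50 in the other lists, so by the median E11.5 sample 3 did not stand out. Of regions called in all E11.5 lists, 4.56% were called nowhere else in the highest of 4 equal groups by rank and 19.7% in the lowest. The ratio of 0.231 lies under the bound of 0.25 set before the test, as predicted for a higher signal. Its 95% interval of 0.176 to 0.304, demanded only after the value was seen, includes the bound. This interval treats regions as independent and does not measure the spread between lists. The ratio was computed for the E11.5 trio alone, so whether the share falls as much with rank in other trios is not known. This test therefore cannot tell a higher signal apart from other causes. A batch of the E11.5 libraries alone cannot be told apart from the stage, and the stage itself stays open and untested.

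The 186 genes that differed between E11.5 and E12.5 exceed every other split drawn, with 1 of 100 splits as large and 6 genes as the highest other. Other pairs of trios in the same splits reached 50 and 45 genes, so 6 depends on which pairs were drawn for this comparison. A share of 1 of 100 is the smallest these draws can give and was not adjusted over the comparisons, so chance is not excluded. The 186 genes are nonetheless above all of these numbers. A single library may account for most of them, since 16 genes passed in the fit without E11.5 sample 2, 14 of them among the 186, against 140 and 139 without samples 1 and 3, with 119 and 104 among the 186. Calling that follows gene density is left open: the genes with fewer calls lie in gene-poor parts of the genome, with a median of 9 gene boundaries within 500 kb at the 11.9th percentile of tested genes, while the genes with more calls lie at the 47.9th. Base composition was not tested, and a change with stage stays open.

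The 362 regions lost between E10.5 and E12.5 were 7.59 times the expected number. With calling odds fitted separately near and away from gene boundaries they were still 3.22 times the expected number. This lies close to the bound set before the test, and so coarse a split can leave part of the effect unadjusted. A lower share of boundary peaks in the E12.5 lists may therefore account for part of the excess. Whether it accounts for the whole is left open. Without E12.5 sample 1, which leaves lists with high numbers in both stages, the ratio was 4.81, which argues against a batch by these numbers as the cause. Differences in signal between libraries and a change with stage stay open.

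For the other comparisons, the 6 genes between E10.5 and E11.5 were reached by 4 of the 100 splits drawn, too near 0.05 for 100 draws to exclude chance, and 1 split gave 50 genes, with E10.5 sample 3 and E12.5 samples 1 and 3 against the 3 E11.5 lists, which points to a structure of the E11.5 lists. Between E10.5 and E12.5 no gene passed, so that 100 of 100 splits gave as many by construction, which decides nothing on chance; 1 split gave 45, with the 3 E12.5 lists against E10.5 sample 3 and E11.5 samples 1 and 2, which points to a structure of the samples. With 10 splits of 6 lists no share under 0.05 can be had: gained and lost regions totalled 927, 935 and 2117 for E12.5 against E10.5, E11.5 against E10.5 and E12.5 against E11.5, with 777, 883 and 1701 as the highest of the other splits, and by count the real split was the 1 largest of the 10 each time. By ratio to the expected number it was 1.406, 4.204 and 4.821, with 1.619, 1.139 and 1.537 as the highest other, so that for E12.5 against E10.5 it was not the largest (2 of 10 as large). The ratios for E10.5 and E12.5 lists only, 2.25 and 1.69, were reached by 5 and 11 of the 84 trios, with 28.1, the ratio of the E11.5 trio, as the highest other, so by this count chance cannot be excluded. Without the trios of the other 2 stages they were reached by 4 and 9 of 82 (4.88% and 11%, highest other 3.29), so the outcome for E10.5 turns on which trios are counted.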
